A study of Mus musculus with 6 samples.

How the data were processed

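RNA was measured in skin biopsies of 6 C57BL/6 mice, 3 wild type (Tnip1+/+) and 3 knockout (Tnip1-/-), each treated with imiquimod for 2 days. The design text gives 3 mice per genotype, so the replicates were separate animals. Per the labels' protocols, total RNA was extracted with TRIzol, depleted of ribosomal RNA and made into stranded libraries that were read in pairs on an Illumina HiSeq. Untreated skin was not analysed here.

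The deposited values were counts, whole numbers per gene symbol with 1 file per library, and their totals differed between libraries. Per the submitters' processing notes, the tools were CASAVA 1.7, STAR, BWA, HTSeq, limma and R 3.2.3, and the genome build was mm9. The order of these tools, their settings, the strand option of the counter and the gene annotation were not given in the sources used here. Without a stated strand option, reads of overlapping and antisense genes could not be told apart. Counts split between near-identical copies (Krt6a and Krt6b, the Sprr2, Stfa, Defb, Saa, Gbp, histone and haemoglobin genes, pseudogenes and their parents) were treated as uncertain. Each file held 34590 gene symbols and 5 summary lines of the counter. The summary lines took 27.6% to 30.3% of each wild type file and 26.7% to 28.0% of each knockout file, and they were left out of library sizes and tests.

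Everything that follows was computed from these counts. Gene counts summed to 31005554, 29527732 and 24701074 in wild type replicates 1, 2 and 3 and to 25864730, 24448322 and 19529970 in knockout replicates 1, 2 and 3. A gene with 3 counts would stand at 0.0968 to 0.154 CPM (counts scaled to library size) in these libraries, which marks the level below which a gene was not detectable at this depth. Intervals around ratios of few counts are 95% exact intervals and cover counting error only, since reads copied in PCR are not independent molecules. Replicates within a group differed by far more than sampling noise (chi-square per degree of freedom of 30.8 to 124), so no library was treated as a duplicate of another.

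Groups were taken from the labels. Genes were tested in R 4.3.3 with edgeR 4.0.16: TMM factors (0.898 to 1.095), the default filterByExpr filter with the genotype groups, a quasi-likelihood fit without robust dispersion, and Benjamini-Hochberg adjustment over the 16691 genes that passed the filter. A gene was called at an adjusted p under 0.05. Log2 fold changes are knockout minus wild type, and their standard errors (SE) were derived from the fold change and the F statistic. Levels are TMM-scaled CPM given as mean ± SD over 3 libraries.

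The 33 gene lists were fixed before the data were examined, and so were the tests and most alternatives. Lists with at least 5 tested members (32 lists) were tested with camera in limma 3.58.1 on edgeR log2 CPM with a prior count of 2, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. For each list the number of called members is given over all genes tested and adjusted over the list alone. Of the lists, 13 genes were members of more than 1. Genes named in the text are Tnip1, the 8 largest increases and 8 largest decreases among called genes with a mean of at least 1 CPM, groups that do not overlap and no predicted, ribosomal, pseudogene or small RNA name, up to 4 members of each list with the smallest p, and a fixed panel of 22 inflammation and epidermis genes. Il18bp, Il1r2, Irf1, Tnip3, Wars, Ifi27l2a, Ereg, Fosl1, Sprr1a, Ptx3, Defb6, Mmp9, Ncf1, Itgam, Fscn1, Krt10, Krt1, Krt5, Flg2, Isg15, Gjb2, Cd74, Myd88, Il33 and the genes named for wild type replicate 3 were chosen after their values were seen.

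The procedure was tested on simulated data with the means and library sizes of the knockout and wild type comparison, over 16470 genes. It recovered 32% of 100 genes changed by 1 on the log2 scale and 89% of 100 changed by 2. No other genes were changed, whereas 45.1% of tested genes were called in the real data. The recovered shares are therefore not the sensitivity of the real comparison. Of its 130 calls, 9 were false (6.9%), and 0 of 40 lists without a planted change were called. Simulated genes were drawn independently of each other, so the list result does not cover lists whose members move together.

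Alternatives covered DESeq2 1.42.0 size factors and Wald test, library totals alone, upper-quartile factors, limma voom, robust dispersion, no filter and a stricter filter, the replicate number as a block, leaving out each library, and leaving out haemoglobin, mitochondrial, histone and small RNA genes. Further alternatives were a GC and length offset, a muscle and fat score as a covariate, an estimated correlation or fry for the lists, and lists without shared members. A sex covariate, protein-coding genes alone and, for the lists, upper-quartile factors were added after seeing the data. A mouse reference of a later build (GRCm38 with GENCODE annotation) was used for names, gene classes, GC content, length and gene order only, and 97.5% of tested genes had a GC content and length. No coordinates are given because the builds differ.

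The labels name no batch. The library codes in the labels began with IMQ in the 3 wild type libraries and with NORM in the 3 knockout libraries, and what these letters stand for was not given in the sources used here. The labels state imiquimod treatment for all 6 mice, but the codes could also be read as treated against untreated skin. Under that reading every difference between knockout and wild type would include the effect of treatment. As 0 prefixes were held by both groups, a difference in handling or treatment that follows the codes cannot be told apart from genotype. Xist exceeded the Y-linked genes in 2 wild type libraries and 1 knockout library, and the reverse held in 1 and 2. Wild type replicate 2, with Xist high, also held Y-linked reads at 1.37% of the mean of the libraries with Y-linked over Xist, against 0.0471% in wild type replicate 3 and 0.083% in knockout replicate 3.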

Results

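The data were gene counts from skin of mice treated for 2 days with imiquimod, a Toll-like receptor 7 agonist that gives a psoriasis-like inflammation when applied to mouse skin. Of the 6 mice, 3 were wild type and 3 lacked Tnip1, which encodes a ubiquitin-binding partner of A20 that restrains NF-kB signalling. Libraries held 24701074 to 31005554 gene counts in wild type skin and 19529970 to 25864730 in knockout skin (n = 3 each). The question addressed was which transcripts differ between imiquimod-treated skin with and without Tnip1.

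Tnip1 itself was low in all 3 knockout libraries. Its level was 26.4 ± 1.55 CPM in wild type skin (938, 739 and 703 counts) and 1.81 ± 0.230 CPM in knockout skin (47, 37 and 35 counts), so the knockout mean was 6.8% of the wild type mean. Tnip1 fell by 3.87 on the log2 scale (SE 0.16, adjusted p = 5.87e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The labels do not give the deleted part of the gene, and the counts cover the whole gene.

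The skin of the 2 genotypes differed widely. Keratins of stressed epidermis and neutrophil-associated alarmins were among the largest increases in the knockout. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7525 of 16691 tested genes differed (45.1%), of which 3730 were higher and 3795 lower in knockout skin. Of these, 1542 were higher and 2131 lower by at least 1 on the log2 scale. Of tested protein-coding genes, 23.4% were called higher and 21.9% lower. Counts of called list members below are to be read against these shares. The share called either way was below 45.1% in the basal keratinocyte, A20 partner, Toll-like receptor, monocyte, T cell, mast cell and endothelial lists. The same held for the fibroblast, hair follicle, immediate-early and sex-linked lists. The groups did not overlap for 7482 of the called genes and for 9973 of all tested genes, where chance gives 10%. The first principal component held 73.1% of the variance and separated the genotypes. With library totals alone in place of TMM factors, 34.1% of the calls were higher instead of 49.6%, with a shift of -0.155 in the median log2 fold change. With a muscle and fat score as a covariate, 1242 genes were called.

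Among the 8 largest increases was Spink12, a serine protease inhibitor gene, with 6 counts over the wild type libraries and 13.8, 13.9 and 72.7 CPM in the knockout libraries (log2 8.86, SE 1.09, and 7.61 without knockout replicate 3). Krt6b, a keratin of stressed epidermis, rose from 50.3 ± 36.1 to 11370 ± 1445 CPM (log2 7.82, SE 0.65, and 8.57 without wild type replicate 2). Lce3a, a late cornified envelope gene induced in injured epidermis, rose by 7.85 (SE 0.64, with 0.0900, 0.986 and 0.222 CPM in the wild type libraries, and 9.33 without wild type replicate 2), and the cytokine Il19 rose by 7.30 (SE 1.22, with 67.4, 12.8 and 7.36 CPM in the knockout libraries, and 6.68, 7.90 and 5.77 without wild type replicate 1, wild type replicate 2 and knockout replicate 1). S100a9, which encodes a subunit of calprotectin, rose from 38.5 ± 31.5 to 5574 ± 1319 CPM (log2 7.18, SE 0.80, and 8.01 without wild type replicate 2), and the cystatin gene Stfa1 rose by 7.12. The urate oxidase gene Uox rose by 7.72 (SE 1.19, with 385, 132 and 42.3 CPM in the knockout libraries, 6.63 without knockout replicate 1 and 9.21 without wild type replicate 2). The protease gene Tmprss11bnl, with 7 counts over the wild type libraries, rose by 7.60 (SE 0.66). Reads of Krt6a and Krt6b, and of the Stfa genes, may be split differently than the transcripts because the copies are near-identical. The largest decrease was that of the imprinted gene Nnat, from 39.5 ± 23.2 to 0.188 ± 0.164 CPM (log2 -7.72, -8.32 without knockout replicate 1 and -7.08 without knockout replicate 2). Serpinb6e (-6.52), Serpina3b (-5.57, and -6.30 without knockout replicate 2), the carbonic anhydrase gene Car6 (-5.66), H2-M5 (-5.41) and the mast cell receptor gene Mrgprb3 (-4.92, and -4.31 and -6.46 without knockout replicates 1 and 2) fell too (log2). Krtap3-2 had 224 counts over the wild type libraries and 1 over the knockout libraries (ratio 165, interval 29.2 to 6530; log2 -6.98, and -9.05 without knockout replicate 2, the library with that count), and P2rx2, an ATP-gated channel gene, had 314 and 2 (ratio 115, interval 31.7 to 957).

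**Figure D1:**
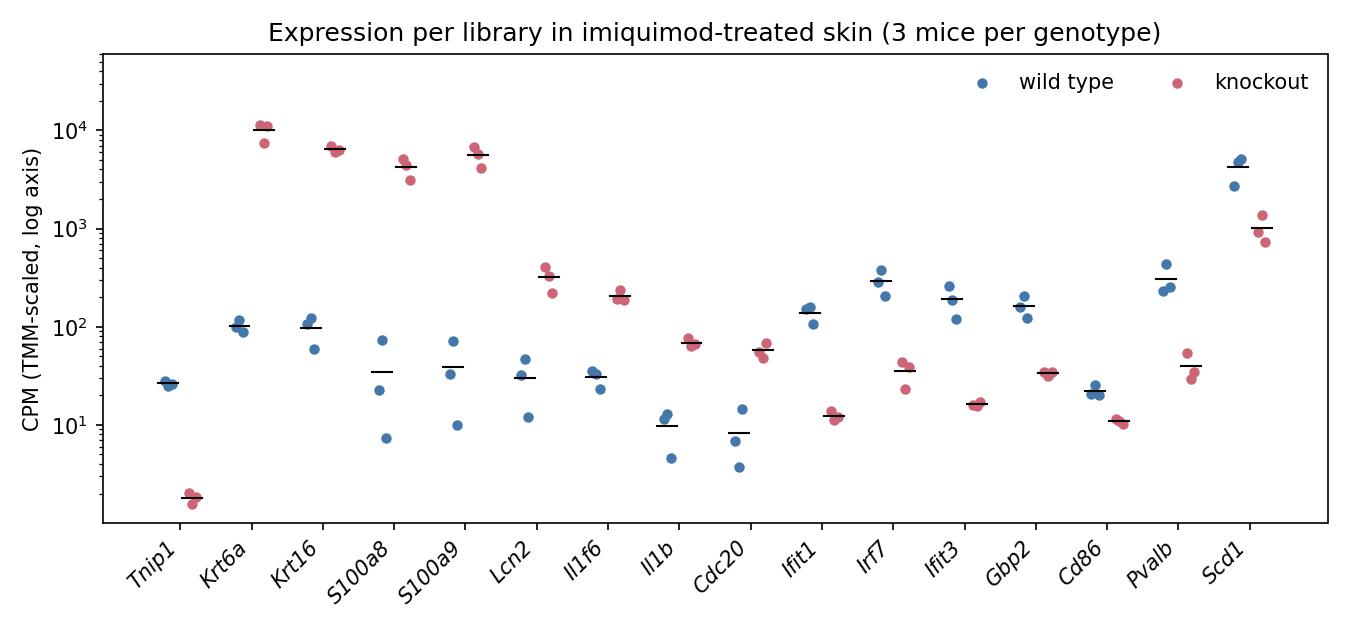
TMM-scaled CPM (log axis) of 16 genes in each wild type (blue) and knockout (red) library; black bars are means of 3 libraries. Tnip1 stood at 26.4 CPM in wild type and 1.81 CPM in knockout skin, Krt6a at 101.5 and 9974 CPM, and Ifit1 at 139 and 12.3 CPM.

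Epidermal stress and hyperproliferation genes rose almost as a block. Of 34 tested members, 31 rose and 0 fell (31 and 0 adjusted over the list alone), with a median log2 fold change of 5.13. Krt6a rose from 101.5 ± 15.2 to 9974 ± 2142 CPM, and Krt16, another keratin of wounded and psoriatic epidermis, from 96.6 ± 33.1 to 6399 ± 452 CPM. Lce3f rose by 6.96 (SE 0.16), Stfa3 by 5.13 (SE 0.20), and the connexin gene Gjb2 by 5.32. The 3 members that did not pass the test were Ereg (0.34), Fosl1 (0.61) and Sprr1a (0.12), and the value for Sprr1a turned to -0.02 with library totals alone. Fosl1 passed without wild type replicate 1 (1.79). By limma's camera test the stress list was higher (adjusted p = 3.74e-17, and adjusted p = 0.591 with an estimated correlation).

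Antimicrobial and alarmin genes rose as well, 16 of 18 with 0 lower (17 and 0 adjusted over the list alone) and a median log2 fold change of 4.69. Chi3l3, a chitinase-like gene of activated myeloid cells, rose from 1.07 ± 0.115 to 138 ± 27.8 CPM. Slpi, a secreted protease inhibitor, rose by 5.91, the beta-defensin gene Defb4 by 6.63 (7.28 without wild type replicate 2) and S100a7a, the mouse psoriasin gene, by 6.06. S100a8, which encodes the other subunit of calprotectin, rose from 34.7 ± 35 to 4232 ± 1025 CPM (log2 6.93, and 8.14 without wild type replicate 2). Lcn2, a siderophore-binding protein gene, rose from 30.3 ± 17.4 to 319 ± 95.5 CPM. Ptx3 (2.49) and Defb6 (-0.05) did not pass the test, although Ptx3 passed without knockout replicate 3 (2.98) and stood at 0.84 without knockout replicate 1. The antimicrobial list was higher by camera (adjusted p = 1.63e-09, and adjusted p = 0.591 with an estimated correlation).

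Late differentiation genes of the cornified layer moved both ways. Of 39 members, 14 rose and 11 fell (16 and 11 adjusted over the list alone). Repetin (Rptn) rose from 336 ± 68.2 to 3079 ± 568 CPM, the transglutaminase gene Tgm3 rose by 4.60, the ceramide synthase gene Lass3 by 1.92 and the suprabasal keratin gene Krt1 by 1.34. The late envelope gene Lce1m fell from 335 ± 39.1 to 17.1 ± 11.7 CPM, and the filaggrin-like gene Flg2 fell by 3.08, with -4.99 and -3.83 for these genes without knockout replicate 2. Krt10, the partner of Krt1, fell by 0.95. Loricrin (Lor, -0.67, adjusted p = 0.11) and filaggrin (Flg, 0.94, adjusted p = 0.0738) did not pass the edgeR test with Benjamini-Hochberg adjustment, and camera did not call the list (adjusted p = 0.308). Without knockout replicate 2 Lor passed (-1.07), without knockout replicate 1 Flg passed (1.27) and 16 members were higher and 7 lower. Krt10 lost its call without wild type replicate 1 or 3 or knockout replicate 1 or 3 (-0.84, -0.94, -1.06 and -0.69).

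Basal keratinocyte and adhesion genes showed a smaller change. Of 18 members, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 0.61. Krt14 rose from 1985 ± 772 to 11550 ± 2098 CPM, its partner Krt5 rose by 1.19 and the desmoglein gene Dsg3 by 1.82. The 2 that fell were Krt15, a keratin of resting basal cells, by 3.08 and Dst, which encodes a hemidesmosomal plakin, by 1.15. Camera gave an adjusted p of 0.0449 (adjusted p = 0.758 with an estimated correlation). This call ended without wild type replicate 2 (adjusted p = 0.122), with fry (0.221), the stricter filter (0.0549), the sex covariate (0.0655) or protein-coding genes alone (0.053). Krt5 lost its call with library totals alone (1.03) and without wild type replicate 2 or 3 or knockout replicate 2 or 3 (adjusted p = 0.0519, 0.0729, 0.0632 and 0.0773, same edgeR test with Benjamini-Hochberg adjustment).

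Cytokines of the IL-23 and IL-17 axis were higher in part. Of 17 tested members, 8 rose and 1 fell (10 and 1 adjusted over the list alone). Il23a, which encodes a subunit of IL-23, rose by 4.08 (SE 0.63) from 0.128 ± 0.112 to 2.30 ± 0.527 CPM. The IL-20 family genes Il24 and Il19 rose by 5.50 (SE 0.91; 4.90, 6.99 and 4.70 without wild type replicate 1, wild type replicate 2 and knockout replicate 1) and 7.30 (SE 1.22), and Il17c, an epithelial IL-17 cytokine gene, rose by 4.68 (SE 0.78, and 6.55 without wild type replicate 1). Il23a, Il24, Il19 and Il17c had 12, 5, 16 and 13 counts over the wild type libraries, so the sizes of these increases rest on few counts. Il17f rose by 4.66 (17.6, 3.86 and 0.731 CPM in the knockout libraries and 0.222 to 0.340 CPM in wild type), and Il6 rose by 3.44. Il17a did not pass the edgeR test with Benjamini-Hochberg adjustment (3.37, adjusted p = 0.0557), and neither did Il12b (1.5, adjusted p = 0.0631) or Ccl20 (0.93, adjusted p = 0.0868). Il22 was too low to test, with 2, 0 and 0 counts in wild type and 70, 26 and 2 in knockout libraries (ratio 66.7, interval 18 to 558). As a whole the IL-23 and IL-17 list was higher by camera (adjusted p = 0.007, and adjusted p = 0.591 with an estimated correlation). Il17f stood at 2.99 without knockout replicate 1, and Il17a at 1.84 without that library and 5.00 without wild type replicate 1. Il17f lost its call without wild type replicate 2 (4.79), and Il6 lost it without wild type replicate 1, 2 or 3 or knockout replicate 1 (3.85, 3.48, 3.13 and 2.16). Without knockout replicate 3, Il17a (3.90), Il12b (1.94) and Ccl20 (1.21) passed.

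IL-1 and IL-36 family genes were mostly higher. Of 17 members, 9 rose and 2 fell (9 and 2 adjusted over the list alone), with a median of 1.28. Il1f6, the gene of IL-36 alpha, rose from 30.8 ± 6.57 to 205 ± 26.6 CPM and Il1f9, that of IL-36 gamma, from 60.1 ± 7.70 to 243 ± 15.7 CPM. Il1f5, which encodes the IL-36 receptor antagonist, rose by 1.72 and Il1f8 by 1.64. Il1b rose by 2.83 (SE 0.36) and the alarmin gene Il33 by 2.42. The 2 that fell were Il18bp, which encodes an IL-18 inhibitor, by 1.69 and the decoy receptor gene Il1r2 by 0.82. The IL-1 and IL-36 list was higher by camera (adjusted p = 8.29e-04, and adjusted p = 0.591 with an estimated correlation). Without wild type replicate 1 or 3 or knockout replicate 2 or 3 the number lower was 1, as Il1r2 lost its call in these fits (-0.50, -0.92, -0.78 and -0.66).

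Chemokine genes split by direction, 8 higher and 7 lower of 26 (8 and 7 adjusted over the list alone). The neutrophil chemoattractant genes Cxcl3 (3.58), Cxcl2 (3.75) and Cxcl1 (3.17) rose, as did the monocyte chemoattractant gene Ccl8 (1.56). The keratinocyte chemokine gene Ccl27a fell from 36.1 ± 6.38 to 4.61 ± 0.331 CPM, and the interferon-inducible Cxcl10 fell by 2.32. The chemokine list was not called by camera (adjusted p = 0.811), and its direction was higher where that of fry was lower. Cxcl1 lost its call without wild type replicate 2 or 3 or knockout replicate 1 (2.95, 2.79 and 2.64) and stood at 4.17 without wild type replicate 1.

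NF-kB target genes were higher by a modest amount, 14 of 30 with 2 lower (17 and 2 adjusted over the list alone) and a median of 0.61. The colony-stimulating factor gene Csf3 rose by 5.26 (SE 0.98, with 4.91, 2.41 and 0.731 CPM in the knockout libraries). Csf3 had only 6 counts over the wild type libraries, and stood at 4.51 without knockout replicate 1 and 6.91 without wild type replicate 1. The anti-apoptotic gene Bcl2a1b rose by 2.19, Tnfaip2 by 1.93, Nfkb1 by 0.80 and Tnf by 0.94. Tnfaip3, the gene of A20, stood at 0.61 (adjusted p = 0.267) and Nfkbia, that of the NF-kB inhibitor alpha, at 0.88 (adjusted p = 0.0581), so neither passed the edgeR test with Benjamini-Hochberg adjustment. Irf1 fell by 0.68 and Tnip3, a relative of Tnip1, by 0.97. The NF-kB list was higher by camera (adjusted p = 0.00398, and adjusted p = 0.649 with an estimated correlation), and fry did not (0.0988). The number higher was 9, 6, 7 and 10 without wild type replicate 2, wild type replicate 3, knockout replicate 1 and knockout replicate 2, and 9 with 4 lower with library totals alone; 1 was lower without any single knockout library. Tnf lost its call without wild type replicate 3 or knockout replicate 2 or 3 (0.77, 0.87 and 0.86), Tnip3 without knockout replicate 1 or 3 (-0.98 and -0.84) and Irf1 without knockout replicate 2 (-0.57), whereas Tnfaip3 passed without wild type replicate 1 (1.22) and Nfkbia without wild type replicate 1 or knockout replicate 3 (1.18 and 1.13).

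The partners of A20 in ubiquitin and kinase signalling moved little in size (median log2 fold change 0.20), and were called about as often as other genes. Of 24 members, 6 rose and 4 fell (6 and 4 adjusted over the list alone), among them Tab2 (-0.79), Optn (-0.76) and Fam105b (0.52), the gene of the deubiquitinase OTULIN. The list was not called by camera (adjusted p = 0.416). With library totals alone 2 were higher and 7 lower. Without wild type replicate 3, knockout replicate 1, knockout replicate 2 and knockout replicate 3 the counts were 3 and 3, 3 and 2, 3 and 2, and 2 and 3.

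In the Toll-like receptor list, 4 of 24 rose and 3 fell (3 and 2 adjusted over the list alone). Tlr2 rose by 1.10, its co-receptor gene Cd14 by 1.69 and the adaptor gene Myd88 by 1.05. Tlr3 fell by 1.17 and Irf7 by 3.05. Tlr7, which encodes the receptor for imiquimod, stood at 14.2 ± 6.32 CPM in wild type and 17.5 ± 2.28 CPM in knockout skin (0.30, adjusted p = 0.436 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). This list was not called by camera (adjusted p = 0.974), and its direction was higher although the median (-0.04) and mean (-0.05) were below 0. Tlr7 passed without wild type replicate 2 (0.72).

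Type I interferon-inducible genes fell nearly without exception. Of 30 members, 0 rose and 29 fell (0 and 29 adjusted over the list alone), with a median of -1.78. Ifit1 fell from 139 ± 29.0 to 12.3 ± 1.42 CPM, Ifit3 from 191 ± 70.8 to 16.3 ± 0.716 CPM and Ifi44 by 3.56. Isg15, the gene of a ubiquitin-like modifier induced by interferon, fell by 2.92, and Irf7, a transcription factor gene that amplifies the interferon response, fell from 290 ± 87.5 to 35.1 ± 10.7 CPM. Ifi27l2a did not pass the test (-0.83). The type I interferon list was lower by camera (adjusted p = 6.24e-12, and adjusted p = 0.591 with an estimated correlation). With the muscle and fat covariate 13 members were lower.

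Interferon-gamma-inducible genes were lower too, 15 of 25 with 1 higher (16 and 1 adjusted over the list alone) and a median of -1.46. The guanylate-binding protein genes Gbp2 (-2.27), Gbp3 (-2.54) and Gbp6 (-2.38) and the GTPase gene Tgtp1 (-2.36) fell. The member that rose was Wars (0.52), the tryptophanyl-tRNA synthetase gene. The list was lower by camera (adjusted p = 4.28e-05, and adjusted p = 0.591 with an estimated correlation). Wars was not called with library totals alone (0.35), nor without wild type replicate 2 or 3 or any single knockout replicate (0.43, 0.47, 0.43, 0.59 and 0.56). The muscle and fat covariate left 8 lower.

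Genes of MHC class II and antigen presentation fell in 11 of 15 cases with 0 higher (12 and 0 adjusted over the list alone), with a median of -1.16. The dendritic cell maturation genes Cd83 and Cd86 fell by 1.38 and 1.01, the peptide-loading genes H2-DMb2 and H2-DMa by 1.96 and 1.02, and the invariant chain gene Cd74 by 1.35. Camera called the list lower (adjusted p = 0.00143, and adjusted p = 0.591 with an estimated correlation). The number lower was 6, 7, 6 and 7 without wild type replicate 2 (with 1 higher), wild type replicate 3, knockout replicate 2 and knockout replicate 3, and Cd74 lost its call without knockout replicate 2 (-1.24). The muscle and fat covariate left 2 lower.

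Among leukocyte markers, those of neutrophils stood out. Of 22 members, 19 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 3.48. BC100530, a stefin-like gene, rose from 68.4 ± 18.4 to 4150 ± 166 CPM, the collagenase gene Mmp8 by 4.84, the C-type lectin receptor gene Clec4e by 4.22 and the chemokine receptor gene Cxcr2 by 3.07. Mmp9 (0.86), Ncf1 (0.44) and Itgam (0.46) did not pass, although all 3 passed without wild type replicate 2 (1.18, 0.60 and 0.91) and Mmp9 also without knockout replicate 2 (1.07). S100a8 and S100a9 are in this list and in the antimicrobial list. Camera called the neutrophil list higher (adjusted p = 4.88e-10, and adjusted p = 0.591 with an estimated correlation).

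Monocyte and macrophage markers moved less, 8 of 24 higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 0.34. The lysozyme gene Lyz2 rose from 415 ± 80.5 to 920 ± 109 CPM, the mannose receptor gene Mrc1 by 1.09, Lilrb4 by 0.96 and F13a1 by 0.78. Camera did not call this list (adjusted p = 0.293), although it did without wild type replicate 2 (adjusted p = 0.0455). With library totals alone 7 were higher and 5 lower. The counts were 5 and 0 without wild type replicate 1, 5 and 2 without wild type replicate 3, 4 and 1 without knockout replicate 1 and 5 and 1 without knockout replicate 3, and F13a1 lost its call without knockout replicate 2 (0.65).

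Dendritic and Langerhans cell markers included 6 of 15 that fell and 2 that rose (6 and 2 adjusted over the list alone). Langerin (Cd207), a marker of Langerhans cells, fell from 16.5 ± 4.31 to 2.27 ± 1.13 CPM. Flt3 fell by 1.48 and Xcr1, a marker of cross-presenting dendritic cells, by 2.13. The members that rose were Cd24a (1.7), which keratinocytes also express, and Fscn1 (0.83), which encodes an actin-bundling protein. Camera did not call the list (adjusted p = 0.0874). Its camera adjusted p was 0.0252, 0.0334 and 0.0424 without knockout replicate 1, 2 and 3, 0.0282 without a filter and 0.591 with an estimated correlation. Fry, a different test, gave 0.0378. The numbers higher and lower were 1 and 4 without wild type replicate 2, and 1 and 5 without wild type replicate 3 or knockout replicate 3, and Fscn1 lost its call in each of these 3 fits (0.68, 0.84 and 0.65) and with library totals alone (0.67).

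T cell markers showed no common direction, with 4 of 23 higher and 4 lower (2 and 3 adjusted over the list alone). Trat1 and Thy1 fell by 2.58 and 1.43, Cd3e fell by 1.06 and Zap70 rose by 1.07. By camera the T cell list was not called (adjusted p = 0.974), and the median (0.15) and mean (-0.06) differed in sign. The numbers higher and lower were 1 and 5, 0 and 2, and 1 and 2 without wild type replicates 1, 2 and 3, and 2 and 2, 0 and 5, and 2 and 2 without knockout replicates 1, 2 and 3. With library totals alone they were 1 and 4. Cd3e lost its call without wild type replicate 2 or 3 or knockout replicate 1 or 3 (-0.92, -1.06, -1.08 and -0.89), and Zap70 without wild type replicate 2 or knockout replicate 2 (1.00 and 0.85).

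Of 4 tested B and plasma cell genes, too few for a list test with all libraries, 3 rose and 0 fell (3 and 0 adjusted over the list alone), namely Blk (1.6), Cd22 (1.35) and the immunoglobulin J chain gene Igj (2.30, with 10.9, 64.0 and 14.7 CPM in the knockout libraries, and 1.10 without knockout replicate 2). In fits where enough members passed the filter, camera called this list higher without a filter (adjusted p = 0.0472) and without knockout replicate 1 (0.0255) or 3 (0.031), and not without wild type replicate 1, 2 or 3 (0.139, 0.054 and 0.0516). The number was 1 without wild type replicate 1 or 3, Igj lost its call without any single wild type library (2.43, 2.20 and 2.31), and Cd22 without wild type replicate 1 or 3 or knockout replicate 2 or 3 (1.23, 1.17, 1.32 and 1.24). Of 14 mast cell markers, 4 rose and 1 fell (4 and 1 adjusted over the list alone). The histidine decarboxylase gene Hdc (1.89), Tph1 (2.27) and Fcer1a (1.98) rose and Mrgprb2 (-1.33) fell. Camera did not call the mast cell list (adjusted p = 0.933), whose median (-0.38) and mean (0.27) differed in sign.

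Cell cycle genes rose in 23 of 30 cases with 0 lower (26 and 0 adjusted over the list alone), with a median of 1.32. The mitotic genes Cdc20 and Ccnb1 rose by 2.78 and 2.35, the ribonucleotide reductase gene Rrm2 by 1.72 and the replication licensing gene Mcm3 by 1.09. Wild type replicate 3, the library with high follicle genes, had a mean cell cycle score (log2, relative to the mean of all libraries) of 0.143, against -1.06 and -1.33 in wild type replicates 1 and 2, and without it all 30 members were higher, Cdc20 by 3.45 and Ccnb1 by 3.08. Camera called the list higher (adjusted p = 5.94e-07, and adjusted p = 0.591 with an estimated correlation), and fry did not (0.0676). The number called was 14 with library totals alone, 7, 8, 15, 11 and 6 without wild type replicate 1, wild type replicate 2, knockout replicate 1, knockout replicate 2 and knockout replicate 3, and 0 with the muscle and fat covariate.

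Replication-dependent histone genes rose in 21 of 25 cases with 0 lower (23 and 0 adjusted over the list alone) and a median of 1.83, with Hist1h1c at 1.77, Hist1h4c at 1.84 and Hist1h2be at 2.20. Wild type replicate 3 again stood apart, with a mean histone score of 0.062 against -1.28 and -1.676 in wild type replicates 1 and 2. Camera called the list higher (adjusted p = 7.27e-07, and adjusted p = 0.591 with an estimated correlation). The number was 12, 13 and 12 without wild type replicate 1, wild type replicate 2 and knockout replicate 3, and 1 with the muscle and fat covariate. These transcripts mostly lack poly(A) tails and were captured because the libraries were made from total RNA.

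Skeletal muscle and adipocyte genes were lower in knockout skin. Of 25 skeletal muscle genes, 21 fell and 0 rose (21 and 0 adjusted over the list alone), with a median of -1.47. Parvalbumin (Pvalb) fell from 308 ± 113 to 39.4 ± 13 CPM, myoglobin (Mb) by 2.35, Tcap by 2.08 and Tnnc2 by 1.72. Of 19 adipocyte genes, 10 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -1.72, among them the glycerol channel gene Aqp7 (-2.97) and the lipid droplet genes Plin4 (-2) and Pnpla2 (-1.85). Camera called both lists lower: muscle at an adjusted p of 1.44e-06 (adjusted p = 0.591 with an estimated correlation) and adipocyte at 0.00286 (adjusted p = 0.596 with an estimated correlation, 0.0797 with fry). Knockout replicate 2 had the lowest mean of the adipocyte genes (-3.23 on the log2 scale relative to the mean of all libraries, against -0.03 and -0.09 in the other knockout libraries). Without wild type replicate 2, and with the replicate block, 6 adipocyte genes were called lower.

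Sebaceous gland genes fell in 9 of 18 cases with 0 higher (10 and 0 adjusted over the list alone), with a median of -0.94. Scd1, a fatty acid desaturase gene, fell from 4208 ± 1291 to 1012 ± 334 CPM, its relative Scd3 by 4.24 (-4.96 without knockout replicate 2) and the wax synthase gene Awat2 by 2.52. Nerve and Schwann cell genes fell in 10 of 13 cases with 0 higher (12 and 0 adjusted over the list alone), including the myelin gene Pmp22 (-0.95). Camera called both lower: sebaceous at an adjusted p of 0.00335 (adjusted p = 0.596 with an estimated correlation, 0.0676 with fry) and nerve at 5.49e-04 (adjusted p = 0.591 with an estimated correlation). The number lower was 5 for sebaceous genes without wild type replicate 3 or knockout replicate 1 and 5 for nerve genes without knockout replicate 3; with the muscle and fat covariate it was 2 and 0.

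Fibroblast and dermal matrix genes included 9 of 22 that fell and 0 that rose (9 and 0 adjusted over the list alone), such as Dpt (-1.05), Postn (-1.16) and the fibronectin gene Fn1 (-1.24). Camera gave an adjusted p of 0.0706, which was 0.0455, 0.035 and 0.0478 without wild type replicate 2, wild type replicate 3 and knockout replicate 1. It was 0.0458 with limma voom, 0.0472 without a filter, 0.0183 with the sex covariate and 0.591 with an estimated correlation. Fry, a different test, gave 0.0405. With wild type replicate 1 left out the camera value was 0.395, and 4 members were higher and 8 lower. Endothelial markers moved both ways, 4 of 18 higher and 3 lower (4 and 3 adjusted over the list alone), with the selectin gene Selp at 2.37 and the angiopoietin receptor gene Tek at -1.10. Camera did not call them (adjusted p = 0.627), and with library totals alone 2 were higher and 6 lower. The numbers higher and lower were 2 and 1, 4 and 1, and 2 and 4 without wild type replicates 1, 2 and 3, and 3 and 1, 2 and 2, and 1 and 2 without knockout replicates 1, 2 and 3.

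Some genes of the growing hair follicle were highest in wild type replicate 3. In that library Krt25, Krt71 and Shh had 420, 418 and 173 counts, against 28, 29 and 11 in wild type replicate 1, 6, 9 and 9 in wild type replicate 2 and 5 or fewer in each knockout library. Of 10 tested hair follicle genes 1 rose (Krt84, 1.85) and 3 fell (1 and 3 adjusted over the list alone), namely Krt32 (-3.98), Lef1 (-2.10) and Krt28 (-3.67). Of 6 melanocyte genes 4 fell and 0 rose (5 and 0 adjusted over the list alone), namely Mitf (-0.96), Dct (-2.66), Pmel (-2.80) and Tyrp1 (-2.65). The mean score of the melanocyte genes was also highest in wild type replicate 3 (2.299, against 0.15 and 0.295 in wild type replicates 1 and 2; log2, relative to the mean of all libraries). Camera called neither list (adjusted p = 0.526 and 0.0656). Without wild type replicate 3, 2 melanocyte genes were lower, and without any single knockout library 1 was. The melanocyte list had a camera adjusted p of 0.0139, 0.044 and 0.0365 without wild type replicate 1, wild type replicate 3 and knockout replicate 1. It was 0.0495 with the replicate number as a block, 0.0237 without a filter and 0.591 with an estimated correlation. Fry, a different test, gave 0.0405 for this list. The hair follicle list had a camera adjusted p of 0.0472 without a filter and 0.922 with an estimated correlation. Without wild type replicate 2, 5 hair follicle genes were lower, and without wild type replicate 3, 2 were higher. Dct stood at -1.37 without wild type replicate 3 and lost its call without any single knockout library (-2.96, -2.51 and -2.52), Pmel without these or wild type replicate 3 (-3.10, -2.74, -2.58 and -1.16), and Tyrp1 without these or wild type replicate 2 or 3 (-2.87, -2.35, -2.76, -3 and -1.02). Krt28 lost its call without knockout replicate 1 or 3 (-3.35 and -3.45). Without wild type replicate 3, Lef1 and Krt28 stood at -1.42 and -2.30, and without knockout replicate 2, Krt32 and Krt28 at -5.01 and -4.42.

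Lists fixed as checks of the samples also moved. All 13 mitochondrially encoded genes fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -1.58, for example mt-Cytb from 1261 ± 478 to 408 ± 30.9 CPM. Their mean score (log2, relative to the mean of all libraries) in the wild type libraries (0.138, 1.309 and 0.576) ran beside that of the skeletal muscle genes (0.273, 1.361 and 0.576), whose median was -1.47. In the knockout libraries the scores did not run together (-0.731, -0.575 and -0.717 for mitochondrial and -0.592, -1.163 and -0.456 for muscle genes). Red blood cell genes rose in 7 of 9 cases with 0 lower (8 and 0 adjusted over the list alone), including Slc4a1 (3.52) and Hbb-b2 (2.23). Camera called the mitochondrial list lower (adjusted p = 1.6e-04, and adjusted p = 0.591 with an estimated correlation) and the red blood cell list higher (adjusted p = 0.00373, and adjusted p = 0.591 with an estimated correlation). The red blood cell count was 4 without wild type replicate 1, wild type replicate 3 or knockout replicate 2. Of 16 immediate-early and heat shock genes, 3 rose and 0 fell (0 and 0 adjusted over the list alone), namely Hspa1b (0.81), Jun (0.36) and Dnajb1 (0.62), and camera did not call the list (adjusted p = 0.303) except without wild type replicate 1 (0.0139). Jun and Dnajb1 lost their calls with library totals alone (0.20 and 0.46). The number higher was 6 without wild type replicate 1 and 1 without wild type replicate 3, knockout replicate 1 or knockout replicate 2. Jun lost its call in these 4 fits (0.40, 0.31, 0.35 and 0.32), and Dnajb1 without wild type replicate 2 or 3 or any single knockout library (0.44, 0.60, 0.66, 0.69 and 0.55). Of 5 tested sex-linked genes 0 differed (0 adjusted over the list alone), and both groups held both sexes.

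**Figure D2:**
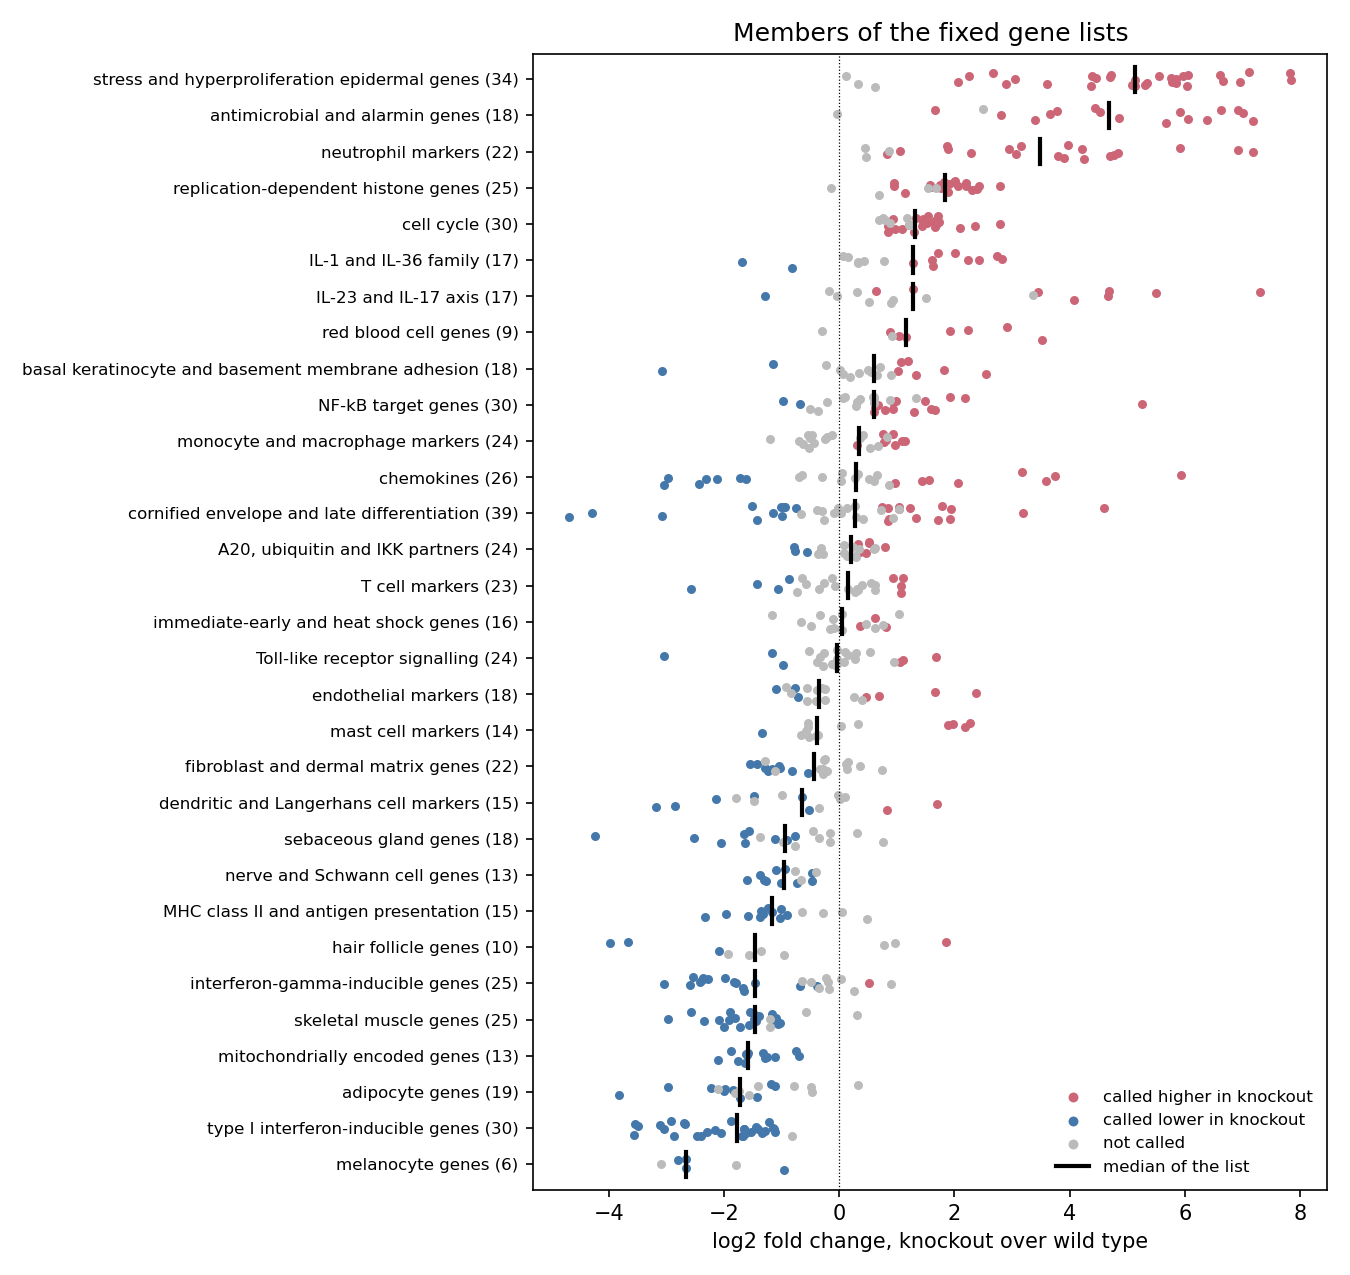
Log2 fold change (knockout over wild type, horizontal axis) of each tested member of the fixed lists, with the number of tested members in brackets; red and blue points passed the edgeR test at an adjusted p under 0.05, grey points did not, and black bars are list medians. The stress and hyperproliferation list has a median of 5.13 and the type I interferon list one of -1.78.

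Over all lists, camera called 18 of 32 with the preset correlation, 10 higher and 8 lower. With an estimated correlation 0 of the 32 lists were called, while fry, which asks whether the members of a list move on balance one way, called 16.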

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

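Of the tests in this part, those of the epidermal and tissue pattern and those of leukocytes, library codes and Y-linked reads were chosen after the results were seen, and the interval rules used to read the pseudogene, olfactory receptor, leukocyte and Y-linked values were also set after those values were seen. Intervals around medians in this part are 95% bootstrap intervals over genes or gene pairs. Genes are not independent replicates, so these intervals do not measure the spread between mice.

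The share of reads that the counter called ambiguous lay outside the gene counts and was higher in every knockout library than in every wild type library, with means of 1.09 ± 0.170% and 0.733 ± 0.0611% (n = 3 each). The share of reads in no gene was lower in every knockout library (20.31% to 22.47%) than in every wild type library (23.79% to 25.91%). The share of unaligned reads was 6.44% in knockout replicate 1, against 3.37% and 3.50% in knockout replicates 2 and 3 and 3.10% to 4.38% in the wild type libraries.

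Processed pseudogenes made up 18 of the 50 largest decreases and 0 of the 50 largest increases, and 310 of 746 tested were lower and 96 higher. Genomic DNA as a common feature of the wild type libraries was argued against, since olfactory receptor genes held only 1.14 times the summed CPM there. Wild type replicate 2 alone stood higher, at 13.2 CPM, against 8.52 and 7.7 CPM in wild type replicates 1 and 3 and 7.92 to 9.56 CPM in the knockout libraries. The higher no-gene share of the wild type libraries leaves some genomic DNA possible. A difference in mapping or counting between the groups stays open, also because the ambiguous and no-gene shares differ. The median of all processed pseudogenes was -0.46, above the bound of -0.5, which by the rule set beforehand spoke against this explanation. Its interval (-0.55 to -0.38), added later, spans that bound. The median also says little about the large decreases. By at least 16-fold, 36 of 746 processed pseudogenes were called lower and 2 higher. Of 14573 protein-coding genes, 43 were called lower and 102 higher by that much. A change in the parent genes stays open in part: the median of pseudogene minus parent was -0.90 over 134 pairs (interval -1.18 to -0.58), below the -0.5 that this explanation allows but short of the bound of -1 set to exclude it. An effect of genotype on pseudogene transcription was not tested.

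Stress genes of the epidermis rose while muscle and fat genes fell, as a biopsy with more epidermis would also show. A larger epidermal share alone was argued against, as the median of the stress list lay 4.53 above that of the basal keratinocyte list (permutation p = 1e-05, the smallest the resampling can give, over genes, which are not independent replicates). One common dilution of all other tissue was argued against as well, because the medians of the muscle, fat, nerve, fibroblast and endothelial lists spread over 1.37, from fat to endothelium; the permutation test compared muscle with fibroblast genes only (p = 3e-05 over genes). How far less muscle and fat in the knockout biopsies drives the count of calls cannot be told apart from genotype: 1242 genes were called with the muscle and fat score as a covariate, and that score followed genotype (r = -0.81 over the 6 libraries, with the genotype as a 2-level variable). A change of the epidermis with genotype stays open.

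Type I interferon-inducible genes fell while neutrophil and IL-36 genes rose. Scaling was argued against by the size of its effect. Library totals alone, upper-quartile factors and DESeq2 size factors shifted the median log2 fold change of all genes by -0.155, -0.084 and 0.015. These shifts were small against the list median of -1.78. At least 29 of the 30 genes were lower under each of these 3 scalings, a count that such shifts could hardly change. A general loss of leukocytes was argued against, as the monocyte and macrophage median was 0.34 (interval -0.44 to 0.77) and the neutrophil median 3.48, although a loss of dendritic cells alone stays open. A difference in handling or treatment between the sets of libraries cannot be told apart from genotype, because 0 library code prefixes were held by both groups. An effect of Tnip1 loss on the interferon response stays open as a hypothesis.

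Wild type replicate 2 held Y-linked reads at 1.37% of the level of the male libraries, and carry-over from a male knockout library stays open. Krt6a stood there at 0.91 times the CPM expected from that share (118 against 130 CPM), but at 93.2 CPM in the other wild type libraries. S100a8 stood at 74.1 against 65.7 CPM expected and 14.9 CPM in the other wild type libraries. Krt16 (123 against 88.1 CPM) also lay above the expected level. S100a9 (72.3 against 86.1 CPM), Lce3a (0.985 against 1.41 CPM) and Uox (2.04 against 3.54 CPM) lay below it. Wild type replicate 1 also held Y-linked reads (Ddx3y at 129 CPM) and was not tested as a source. Krt6b (91 CPM) fell short of a first bound that left out counting error, and not of the bound with it (49 CPM). The ratio and the bounds count the library's own expression as carry-over, so they cannot decide the question.

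The real grouping called 7525 genes and the highest of the other splits 0. For lists the real grouping called 18 and the other splits 13 to 20, with 5 of the 10 splits, the real one included, calling at least as many. Each of the other splits put libraries of both genotypes into both of its groups. Part of the genotype difference therefore stayed between those groups, and the rest widened the spread within them. The number of lists called by camera did not set the genotype grouping apart from these mixed groupings. As they keep part of the difference, they cannot show what chance alone would give, for lists or for genes. For genes, the 10 possible splits are also too few for a share under 0.05.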

How the results depend on the processing

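A sex covariate, protein-coding genes alone and, for lists, upper-quartile factors were chosen after seeing the data. The number of genes called stayed within 1.5 times the 7525 under every alternative but 1, and ranged from 6416 with the sex covariate to 8090 with DESeq2's Wald test (26 adjusted p values given as NA) apart from the fits with fewer libraries. Leaving out each library in turn gave 5471 to 6866 calls (2792 to 3421 higher, 2679 to 3445 lower), with fewer samples, and 19 to 22 lists. The exception was the muscle and fat covariate, with 1242 calls (655 higher and 587 lower), of which 1199 were main calls in the same direction. That score rises and falls with genotype, which takes up part of the difference by construction. No gene was called in opposite directions in any of the gene settings. Library totals alone gave 7299 calls of which 34.1% were higher, against 49.6%, and shifted the median log2 fold change by -0.155. Tnip1 ranged from -4.03 to -3.73 and was called under each alternative. Lists called numbered 17 to 23 under the alternatives other than the estimated correlation and fry (16), while the estimated correlation called 0 lists (0 higher and 0 lower). The estimates ran from 0.028 to 0.967, so camera with the preset 0.01 assumed less correlation than was estimated. Whether this alone took away the calls was not tested. For 183 named genes, 3394 of 3644 values kept their direction and side of the threshold, 204 fell short of it, 35 newly passed it and 11 changed sign. With the muscle and fat covariate Igj (-0.23), Ccl20 (-0.35), Tnfaip3 (-0.53), Ifi27l2a (0.36) and Ereg (-0.40) changed sign. Sprr1a changed sign with library totals alone (-0.02), with the GC and length offset (-0.03), and without wild type replicate 1 (-0.02) or knockout replicate 3 (-0.04), and stood at 0.31 without wild type replicate 2. Defb6 did so without knockout replicate 1 (0.14) or 3 (0.09) and stood at -0.39 without knockout replicate 2. The cause was not tested, and of these genes Igj alone was called with all libraries. The replicate block gave 6465 calls and 19 lists. Same-numbered libraries correlated at 0.01, -0.21 and 0.19 in their deviations from the group means, and not every library correlated best with its own number, so the numbers were not taken to pair the mice. In simulated data of this design, 32% of the changes of 1 on the log2 scale were recovered and 89% of those of 2. Far fewer genes were changed there than were called here, so these shares are not the sensitivity of the real comparison.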

Other observations

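The tests of gene families, gene neighbours and ribosomal shares in this part were not planned, and the families and the ribosomal comparison were chosen after the results were seen. Ribosomal protein genes, which no fixed list covered, were mostly higher in knockout skin. Among 272 families formed from gene symbols, 37 of 48 genes with symbols in Rpl and 32 of 42 in Rps, most of them ribosomal proteins but with kinases of the Rps6k group among the latter, were higher and 1 of each lower (Fisher's exact tests, one-sided, Benjamini-Hochberg adjusted p = 3.08e-13 and 3.2e-11). Of the elongation factor Eef genes, 4 of 8 were higher and 1 lower (adjusted p = 0.512). Mitochondrial ribosomal Mrpl genes were higher in 28 of 46 cases and nucleoporin Nup genes in 16 of 20, with 0 lower in both (adjusted p = 1.86e-06 and 4.86e-06). Small nucleolar RNA genes were higher in 14 of 20 cases (Snora), 20 of 38 (SNORA) and 13 of 23 (Snord), with 0 lower. The same Fisher's tests gave adjusted p = 3.61e-04, 0.00184 and 0.0101. For SNORD genes, 8 of 16 were higher and 0 lower (adjusted p = 0.155). As the library codes followed genotype, a difference in preparation cannot be told apart from genotype here. The mitochondrial import genes of the Timm family were higher in 10 of 11 cases (adjusted p = 1.47e-04), although all 13 mitochondrially encoded genes were lower.

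Skint genes, which encode butyrophilin-like proteins of keratinocytes and thymus, were lower in 9 of 11 cases with 0 higher (adjusted p = 0.00204). Zinc finger Zfp genes were lower in 135 of 342 cases and higher in 16 (adjusted p = 2.45e-10), and cytochrome P450 Cyp genes were lower in 17 of 36 and higher in 5 (adjusted p = 0.0247). Kallikrein Klk genes, which include proteases of the cornified layer, were higher in 7 of 10 with 0 lower (adjusted p = 0.0364). Genes are not independent replicates, so these adjusted p values describe the families and not the mice.

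A hypothesis was that ribosomal protein genes gained reads that pseudogenes lost. The gain of ribosomal protein genes, 1.29 percentage points of the counts, was 3.58 times the loss of 0.36 points on processed pseudogenes, which argues against such a transfer as the whole of the gain. A second hypothesis was that DNA of another strain around the deleted gene changes its neighbours. Of the 100 tested genes nearest to Tnip1, 49 were called (49.0%), against 45.1% of the others (Fisher's exact test, two-sided, p = 0.481), which does not decide the question.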
